A study of Mus musculus with 24 samples.

How the data were processed

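RNA was sequenced from 24 libraries of mouse embryonic stem cells, 12 of wild-type (WT) and 12 of Atf3 knockout (KO) cells, with 3 of each genotype at each of 4 time points: before differentiation (day 0) and on days 3, 6 and 9. Per the labels' protocols, stem cells were kept with leukaemia inhibitory factor and inhibitors of GSK3 and MEK. Poly(A)+ RNA was selected from total RNA with oligo(dT), and NEBNext Ultra II libraries were read in pairs on an Illumina NovaSeq. The medium and factors used to drive differentiation, and the part of Atf3 that was edited, are not given in the sources used here. Whether the 3 libraries of a group came from separate cultures is not stated either, so every p-value measures the spread between these libraries, which may be technical.

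Per the submitters' processing notes, the tools were FastQC 0.11.9, Trimmomatic 0.39, HISAT2 2.2.1, featureCounts 2.0.1, DESeq2 1.30.1 and R 4.1.0, with genome build mm10. The design text speaks of uniquely mapped reads and does not state a strand, so levels of near-identical paralogs and of overlapping genes are less certain. The deposited table gives FPKM (fragments per kilobase of a gene, scaled by library) for 53465 genes, and how the authors computed it is not given in the sources used here. The column of 1 KO day 0 library could be tied to its group but not to a numbered sample, and it was kept as an unnumbered library of that group. The other 23 columns were each tied to 1 sample, and replicate numbers are those of the sample titles.

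With exon lengths from GENCODE vM21, which held 53360 of the identifiers, the FPKM of each library fell on equal steps that were taken as 1 read each. Between 95.5% and 96.9% of values of at most 50 reads, per library, lay within 0.05 reads of a whole number. The sum of the recovered reads was taken as the depth. The FPKM denominators followed median-of-ratios size factors of the recovered reads over 15331 genes to within 0.0328%, so the deposited values were already scaled between libraries in that way. Intervals for shares of reads are 95% Wilson intervals and cover counting error only. The chi-square per degree of freedom between libraries of 1 group was 5.33 to 222, so no pair of libraries was a copy of the other.

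Genes with an FPKM of at least 1 in at least 3 libraries were tested, 15159 in all. Values were taken as log2(FPKM + 1), and limma 3.58.1 in R 4.3.3 was fitted to the 8 groups with a trended prior (16 residual and 4.02 prior degrees of freedom). Fold changes are differences of group means on that scale, which makes them smaller than the true ratio for genes near or under 1 FPKM. Tests were two-sided, with Benjamini-Hochberg adjustment over the genes tested in each comparison and a threshold of 0.05. KO was compared with WT at each day and as a mean over the 4 days. Each later day was compared with day 0 within a genotype. The KO minus WT difference at each later day was compared with that at day 0 (an interaction), and an F test covered all 3 interactions. For Atf3 alone an exact permutation test between 3 KO and 3 WT values was run at each day, for which 0.1 is the smallest p possible. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 was used for the rest.

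Lists of marker genes of stem cells, germ layers, blood, vessel and muscle types, of extraembryonic tissues, and of signalling, stress and metabolic pathways were fixed, 40 in all. Of these, 38 had at least 5 tested members. The 2-cell-like list and the list of Y-linked and X-inactivation genes had fewer and were not tested. Lists were tested against all other genes with camera and its preset inter-gene correlation of 0.01, adjusted over the 38 lists of a comparison. The alternatives were camera with an estimated correlation, fry, and members found in no other list. A list count "adjusted over the list alone" corrects over that list's members.

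The groups, comparisons, lists, tests and the rule for genes named in the text were fixed before the data were examined. The rule takes Atf3 everywhere. It takes the 6 highest and the 6 lowest log2 fold changes of each KO vs WT comparison, and the 4 highest and lowest of each other comparison. These had to pass the threshold, show no overlap between the values of the groups (a condition dropped for the mean and the interactions), and reach a mean FPKM of 5 in the higher group. Predicted genes and clone names were passed over. The rule adds up to 4 passing members of each list described, those with the largest absolute change, or the most abundant member where fewer than 2 passed. A gene named at 1 day may be given at other days. A result that the rule would name is not reported here. Other genes are said to have been chosen after their values were seen.

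Whether equal replicate numbers pair the libraries of both genotypes was checked from the deviations of each library from its group mean, correlated across genes. At day 3 the same-numbered libraries had correlations of 0.655, 0.614 and 0.599, so the numbers pair the libraries at that day. By title number they were 0.120 and -0.106 at day 0, 0.265, -0.259 and -0.467 at day 6, and 0.196, 0.179 and -0.459 at day 9. By column number they were 0.120, 0.262 and 0.0456 at day 0, where pairing stays open. By column number, 7 of 12 WT libraries correlated best with the KO library of their own number, 3, 3, 0 and 1 of 3 by day.

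The gene tests were run on simulated data with the depths of these libraries and a spread estimated for each gene. In these, 100 of 15144 genes were changed 2-fold and 100 changed 4-fold. The changed genes had a mean FPKM of at least 5, so recovery of lower ones was not measured. Genes were drawn independently, so shifts shared by many genes of a library were absent, and false calls may be undercounted. The fit recovered 31% to 45% of the former and 83% to 88% of the latter. It also called 17 to 32 unchanged genes among 134 to 164 calls, a larger share than the nominal 5%, so single genes near the threshold are less certain than their adjusted p. Camera gave 5 of 100 random lists an unadjusted p under 0.05 after deviations from the group means were shuffled gene by gene. That shuffling removes the correlation between genes, so it cannot show how often camera calls lists of correlated genes. With the real values, splits of the libraries other than the real one called a median of 8 lists at day 6 and 11 at day 9.

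Alternatives chosen in advance were a pseudocount of 0.1, no filter on low values, a filter at a mean FPKM of 5, rescaling to equal sums (TPM), another median-of-ratios scaling, limma without a trend, the replicate number as a block, a log2 fold change of at least 1, the compared groups alone, and leaving out each library in turn. Added after seeing the data were a covariate for the share of reads in rRNA-type genes, equal sums without those genes, voom on recovered reads, blocks at day 3 or within each day, array weights, and leaving out replicate 3 of both day 6 groups. Splits of the libraries into groups of the same sizes were counted, the real one always included, 10 for 3 against 3 and 100 where more were possible. Reads as sequenced were not used here.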

Results

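Gene expression was measured by RNA-seq in mouse embryonic stem cells given as Atf3 knockout (KO) and in wild-type (WT) cells, before differentiation (day 0) and at days 3, 6 and 9. Atf3 encodes a stress-inducible transcription factor of the ATF/CREB family. The series was set up to ask how loss of Atf3 affects the formation of mesoderm and of endothelial cells. Each of the 8 groups of genotype and day held 3 libraries. Depth, as reads recovered from the deposited FPKM values, was 7855582 to 25274243 reads per library with a median of 15611794. Between 4.42% (95% interval 4.41% to 4.43%) and 45.6% (45.6% to 45.7%) of a library's reads lay in 3 rRNA-type genes, Gm42418, CT010467.1 and Gm23935. Gm42418 and CT010467.1 overlap on opposite strands of chromosome 17 (from 39846353 to 39848827 in mm10). The highest share was in WT day 6 replicate 3, which was also the library with the fewest reads outside these genes, 4272078 against up to 24157432 in others.

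**Figure D1:**
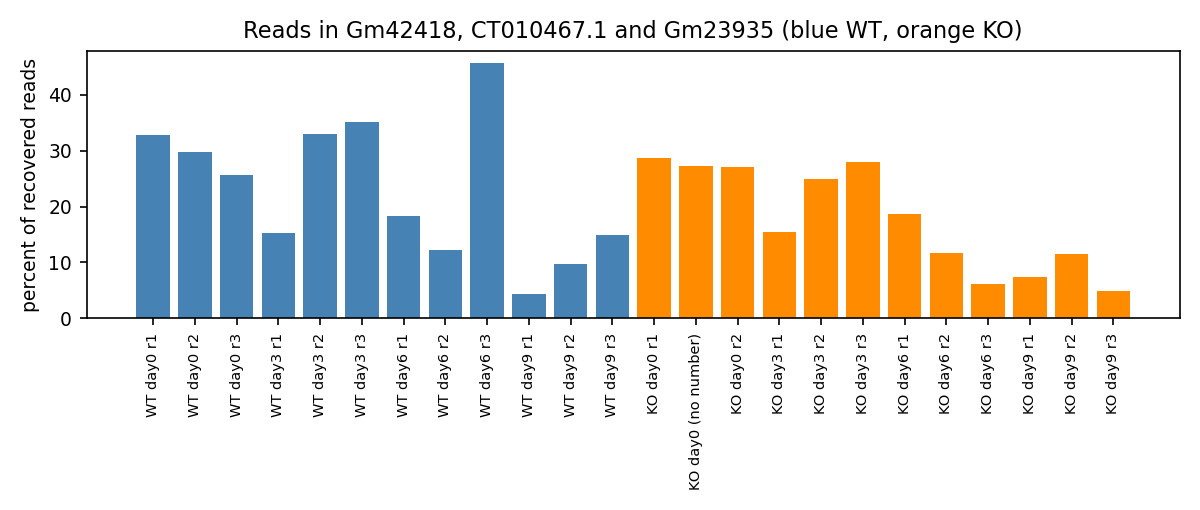
Share of recovered reads (percent, y axis) in Gm42418, CT010467.1 and Gm23935 for each library (x axis), with WT bars in blue and KO bars in orange. The shares run from 4.42% to 45.6%, with the highest bar in WT day 6 replicate 3.

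Atf3 (ENSMUSG00000026628, mm10 chromosome 1, 191170296 to 191218039, minus strand) was lower in KO than in WT cells from day 3 on. Its mean level in WT cells was 1.86 ± 1.04 FPKM at day 0, 10.4 ± 5.36 at day 3, 15.8 ± 7.11 at day 6 and 15.0 ± 1.23 at day 9 (SD, n = 3). In KO cells it was 0.172 ± 0.0417, 0.436 ± 0.182, 1.70 ± 2.15 and 0.534 ± 0.18 FPKM (SD, n = 3). The KO mean was 9.24%, 4.17%, 10.7% and 3.57% of the WT mean. The log2 fold change was -1.23 at day 0 (adjusted p = 1), -2.88 at day 3 (adjusted p = 0.0107), -2.84 at day 6 (adjusted p = 8.13e-04) and -3.38 at day 9 (adjusted p = 5.87e-05). Every KO value lay under every WT value of the same day, and the exact permutation test gave p = 0.1 at each day, the smallest that 3 against 3 allows. In limma the day 3 call was lost with a block within each day (adjusted p = 0.741), under TPM (0.752) and with the compared groups alone (0.622), and the day 6 call in the latter 2 settings (0.175 and 0.799). The day 3 call was also lost without any 1 of 5 of the 6 day 3 libraries (adjusted p up to 0.153). Atf3 read 0.343, 0.578 and 4.17 FPKM in KO day 6 replicates 1, 2 and 3. In WT cells Atf3 rose from day 0 by a log2 fold change of 1.94 to day 3 (adjusted p = 0.00114), 2.54 to day 6 and 2.54 to day 9. In KO cells the same changes were 0.29 (adjusted p = 0.658), 0.92 (adjusted p = 0.0726) and 0.38 (adjusted p = 0.478).

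**Figure D2:**
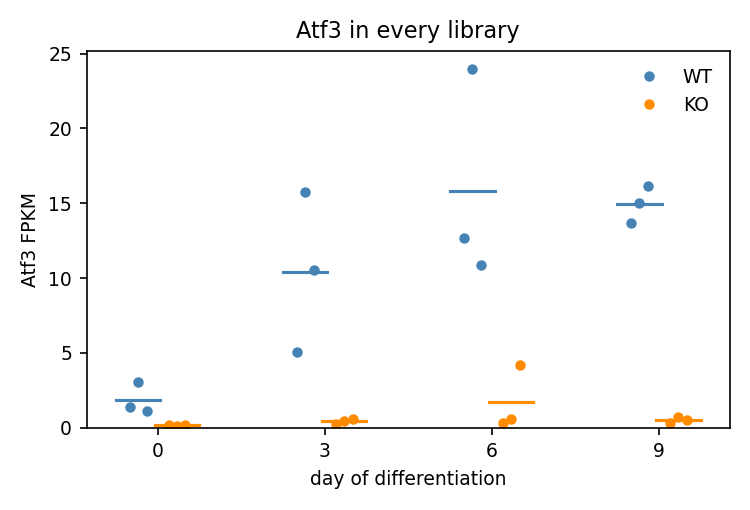
Atf3 level (FPKM, y axis) in every library by day (x axis), with WT in blue and KO in orange, dots for libraries and bars for group means. WT means run from 1.86 to 15.8 FPKM, and 1 KO library, day 6 replicate 3, stands at 4.17 FPKM.

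The WT course, each later day against day 0, shows what these cells became. They lost the naive stem-cell genes and gained genes of mesoderm, smooth muscle and heart. Of 29 naive pluripotency genes, 24 fell by day 3 and 28 by day 6 and by day 9 (list adjusted p = 3.7e-17, 6.0e-19 and 1.0e-17, and 0.0647, 0.0379 and 0.0257 with an estimated correlation). Nanog, a core pluripotency factor, went from 312 to 4.72 FPKM by day 6, and Esrrb, another, from 183 to 2.79. Of 24 mesoderm genes, 22 rose by day 6 (list adjusted p = 1.4e-10, 0.00624 with an estimated correlation) and, at day 9, 19 were higher than at day 0 and 1 lower (list adjusted p = 1.9e-10, 0.00407 with an estimated correlation). Primitive streak genes, which mark the entry into mesoderm, were raised for a time: 12 of 21 rose and 3 fell by day 6 (list adjusted p = 0.00324, 0.179 with an estimated correlation), and the list did not pass at day 9 (adjusted p = 0.638). By day 9, 13 of 16 smooth muscle genes rose and 1 fell (list adjusted p = 3.1e-08), as did 19 of 22 cardiac muscle genes with none lower (list adjusted p = 1.1e-07, 0.0648 with an estimated correlation).

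Vessel, blood and positional genes also changed along the WT course. By day 9, 21 of 37 endothelial genes rose and 9 fell (list adjusted p = 0.0488, 0.639 with an estimated correlation). Kdr, the VEGF receptor of early vessel and blood progenitors, went from 0.25 to 4.39 FPKM (log2 fold change 2.08). Pecam1, an adhesion molecule of endothelium that stem cells also carry, fell from 22.8 to 3.17 FPKM (log2 fold change -2.52). Both were chosen after their values were seen. Of 18 haematopoietic genes, 11 rose and 1 fell (list adjusted p = 0.00379, 0.430 with an estimated correlation), and of 27 Hox genes 22 rose and 1 fell (list adjusted p = 1.8e-09, 0.0256 with an estimated correlation). The genes with the largest rise were Pim2 (4.91), Kif1a (4.69), Bhlhe41 (3.81) and Foxi3 (3.76) at day 3, in log2 fold change. At day 6 they were Spink1 (6.59), H19 (6.32), Hand1 (6.10) and Krt18 (6.05), and at day 9 Rbp4 (6.11), Acta2 (5.92, 11 to 747 FPKM), Hbb-y (5.72) and H19 (5.65). The largest falls were in Mymx (-4.72), Tfcp2l1 (-4.65), Fam25c (-4.55) and Arl14epl (-4.52) at day 3. Rpl10l (-6.05), Nanog (-5.89), Esrrb (-5.83) and Zfp42 (-5.82) followed at day 6, and Esrrb (-5.75), Rpl10l (-5.33), Nanog (-5.21) and Lefty2 (-4.92) at day 9.

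In KO cells, Pim2 (log2 fold change 4.66), Kif1a (4.59), Mir6381 (4.22) and Bhlhe41 (3.63) rose most by day 3, and Fam25c (-4.74), Arl14epl (-4.70), Tfcp2l1 (-4.65) and Mylpf (-4.49) fell most. At day 6 H19 (6.38), Hbb-bh1 (6.32), Hand1 (6.30) and Ttr (6.18) led, with Esrrb (-5.95), Nanog (-5.82), Zfp42 (-5.79) and Tdh (-5.72) lowest. At day 9 Acta2 (7.26), Actc1 (6.73), Tagln (6.36) and Col3a1 (6.20), genes of contractile cells and matrix, led, with Esrrb (-5.52), Tdh (-5.29), Rpl10l (-5.27) and Tfcp2l1 (-5.12) lowest. Genes that changed numbered 3933 at day 3 (1731 up, 2202 down), 7243 at day 6 (3418 up, 3825 down) and 6975 at day 9 (3364 up, 3611 down) in WT cells. In KO cells they numbered 4266 (1803 up, 2463 down), 6625 (3241 up, 3384 down) and 6830 (3391 up, 3439 down). The balance of directions depended on scaling: rescaled to TPM, the split was 5923 up and 897 down at day 9 in WT cells, and 3339 up and 1196 down at day 6 and 5437 up and 956 down at day 9 in KO cells. With equal sums without the rRNA-type genes it was 2630 up and 4453 down at day 6 in WT cells.

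Before differentiation and at day 3, few genes passed between KO and WT cells. At day 0, 2 genes passed in limma (168 at an unadjusted p under 0.05), both chosen after their values were seen. Mir7230 was listed at 0 in every WT library and at 1.78 ± 0.866 FPKM (SD, n = 3) in KO, and Nkx6-3 (log2 fold change -1.0) went from 2.58 ± 0.428 to 0.784 ± 0.173 FPKM. Mir7230 is a microRNA gene, and at such a level a gene that short rests on few reads. With voom on recovered reads 0 genes passed at day 0. No list passed at day 0 (lowest adjusted p = 0.101). At day 3, Atf3 and 1 other gene passed in limma (121 at an unadjusted p under 0.05). Gm22408, also chosen after its values were seen, stood at 1.77 ± 1.09 FPKM (SD, n = 3) in WT and was listed at 0 in every KO library (adjusted p = 0.0359). That level is near the filter of 1 FPKM, and with voom 1 gene passed at day 3. Both day 3 calls were lost without any 1 of WT replicates 2 and 3 and KO replicates 1, 2 and 3, and under TPM, while the day 0 count was 7 without KO replicate 1.

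At day 3, 10 lists passed with the preset correlation, where other splits of the same 6 libraries gave up to 7. Genes of extraembryonic endoderm, the yolk sac lining, were lower as a list (adjusted p = 7.98e-12, 0.198 with an estimated correlation), and so were basement membrane genes (adjusted p = 7.79e-11, 0.141 with an estimated correlation). Lists of mesoderm (adjusted p = 0.0021), definitive endoderm (0.0021), fibroblast and extracellular matrix (0.00365), cardiac muscle (0.0152), BMP and TGF-beta signalling (0.0189), primed epiblast (0.0223) and epithelial-mesenchymal transition (0.0223) were lower too. Oxidative phosphorylation genes were higher as a list (adjusted p = 0.0217). None of these 10 lists passed with an estimated correlation (adjusted p = 0.141 to 0.758), and none of their members passed over all genes. Since replicate numbers paired the libraries at day 3, the number was also used as a block there. With that block the same count of 2 genes passed, but none with a block within each of the 4 days. With the block at day 3, surface ectoderm (adjusted p = 0.0268) and hypoxia and glycolysis (adjusted p = 0.0250) passed as well, both lower in KO. Single libraries turned the direction of a pair of these lists, the primed epiblast list without WT replicate 2 (adjusted p = 0.561) or KO replicate 1 (0.21), and hypoxia and glycolysis without WT replicate 1 (7.47e-04).

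At day 6, several genes that mark the primitive streak and the tissues next to it were lower in KO cells, and several genes of early red blood cells were higher. As lists, streak genes passed with an estimated correlation (adjusted p = 0.0441), while haematopoietic (0.0570), mesoderm (0.0886) and definitive endoderm (0.309) genes did not. T (Brachyury, chromosome 17, 8434423 to 8442496), the factor that marks the streak, was at 15.6 ± 0.991 FPKM in WT and 1.93 ± 2.17 in KO (SD, n = 3; log2 fold change -2.77, adjusted p = 0.036). Cer1 (chromosome 4, 82881751 to 82885148), a secreted Nodal and BMP inhibitor of anterior endoderm, was at 7.63 ± 3.02 FPKM in WT and was listed at 0 in all 3 KO libraries (adjusted p = 7.8e-07). Hbb-bh1 (ENSMUSG00000052217, chromosome 7, 103841637 to 103843164), an embryonic beta-type globin, was at 29.6 ± 24.4 FPKM in WT and 1075 ± 839 in KO (SD, n = 3; log2 fold change 4.73, standard error 0.75, adjusted p = 0.0023). For genes named by rank at days 6 and 9, all 3 KO values lay on one side of the 3 WT values. The KO libraries read 1376, 1721 and 126 FPKM of Hbb-bh1 and the WT libraries 57.8, 15.1 and 16.1.

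The streak and mesendoderm list was lower in KO cells at day 6. Of 21 members, 7 fell and none rose over all genes, 9 fell adjusted over the list alone, and the list adjusted p was 7.43e-11 (0.0441 with an estimated correlation, median log2 fold change -0.39). With the stricter filter the list did not pass (adjusted p = 0.74), and its day 6 interaction turned in direction (0.983). Besides T, these included Lhx1 (-2.42, 11.9 ± 13.8 to 0.677 FPKM), the apelin receptor Aplnr (-2.25, 20.3 ± 6.29 to 3.51 ± 1.63 FPKM) and Mesp1 (-1.88), a factor of early heart and mesoderm progenitors. Definitive endoderm genes overlapped with these, with 4 of 17 lower and none higher, the same 4 adjusted over the list alone: Trh (-3.43, 353 ± 162 to 33.2 ± 20.6 FPKM), Cer1, Lhx1 and Gsc (-1.45). That list had adjusted p = 4.6e-05, and 0.309 with an estimated correlation. In the mesoderm list Mesp1 and Foxc2 (-1.82, 3.31 ± 1.09 to 0.190 ± 0.0754 FPKM) fell, and 2 rose and 5 fell adjusted over the list alone (24 members, list adjusted p = 1.1e-04, 0.0886 with an estimated correlation). The primed epiblast list lost Otx2 (-2.49, 7.03 ± 5.59 to 0.234 ± 0.0444 FPKM) and Fgf8 (-1.84), with 5 of 19 lower adjusted over the list alone (list adjusted p = 4.6e-05, 0.441 with an estimated correlation). Neural ectoderm genes were lower as a list (1 of 11, 4 adjusted over the list alone, adjusted p = 0.00908, 0.0570 with an estimated correlation), with the Notch ligand Dll3 (-2.09) as the member that fell. Of 33 Wnt signalling genes, Sfrp1 (-2.52, 16.9 ± 3.42 to 2.24 ± 1.35 FPKM), Wnt6 (-1.44) and Sp5 (-1.14) fell and Wnt5a (1.08) rose, with 7 lower and 3 higher adjusted over the list alone (list adjusted p = 0.00841, 0.309 with an estimated correlation).

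Red blood cell genes led the genes that were higher in KO cells at day 6. Of 18 haematopoietic genes, 10 rose and none fell, 13 rose adjusted over the list alone, and the list had a median log2 fold change of 1.32 (adjusted p = 1.63e-16, 0.0570 with an estimated correlation). They included the globins Hba-x (4.60, 10.9 ± 9.74 to 433 ± 350 FPKM), Hba-a1 (3.98) and Hbb-bs (3.22). Near-identical copies make the single levels of Hba-a1 and Hbb-bs less certain. Alas2, the first enzyme of haem synthesis in red cells, also rose (2.08, 0.569 ± 0.251 to 7.20 ± 5.16 FPKM). KO replicate 3 stood apart in these genes: Hba-x read 599.6, 668 and 31.1 FPKM in KO replicates 1 to 3 against 22.1, 4.67 and 5.87 in WT, and Alas2 read 9.3, 11 and 1.32 against 0.658, 0.764 and 0.286. Among endothelial genes Tal1 (1.19, 0.593 to 2.92 FPKM), a factor of blood and vessel progenitors, and the receptor Tie1 (0.92) rose and none fell, with 8 of 37 higher and 1 lower adjusted over the list alone (list adjusted p = 0.00292, 0.589 with an estimated correlation). Kdr was at 4.05 FPKM in WT and 2.17 in KO cells and did not pass (adjusted p = 0.522). The integrin Itgb3 (1.58, 1.5 ± 0.405 to 6.86 ± 3.10 FPKM) and the fibrinogen chain Fgb (1.56) rose too. Arterial (adjusted p = 0.192), cardiac muscle (0.379) and smooth muscle (0.283) lists did not pass at day 6.

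In all, 110 genes passed in limma at day 6, 35 higher and 75 lower (1516 at an unadjusted p under 0.05). The share of reads in rRNA-type genes was 18.4%, 12.2% and 45.6% in WT replicates 1 to 3 and 18.6%, 11.6% and 6.10% in KO replicates 1 to 3, and without replicate 3 of both groups 108 genes passed, 66 higher and 42 lower, 53 of them among the 110. The balance of directions turned with KO replicate 3 alone: without it 139 genes passed, 86 higher and 53 lower, 73 of them among the 110, while without WT replicate 3 it was 12 higher and 42 lower. The count was 68 without WT replicate 1, 373 without WT replicate 2, 54 without WT replicate 3 and 34 without KO replicate 2. It was 167 with no filter, 61 with the replicate block, 52 with voom, 49 with a block within each day, 38 under TPM (23 up, 15 down), 12 with a stricter filter, and 0 with the spread taken from the 6 day 6 libraries alone.

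**Figure D3:**
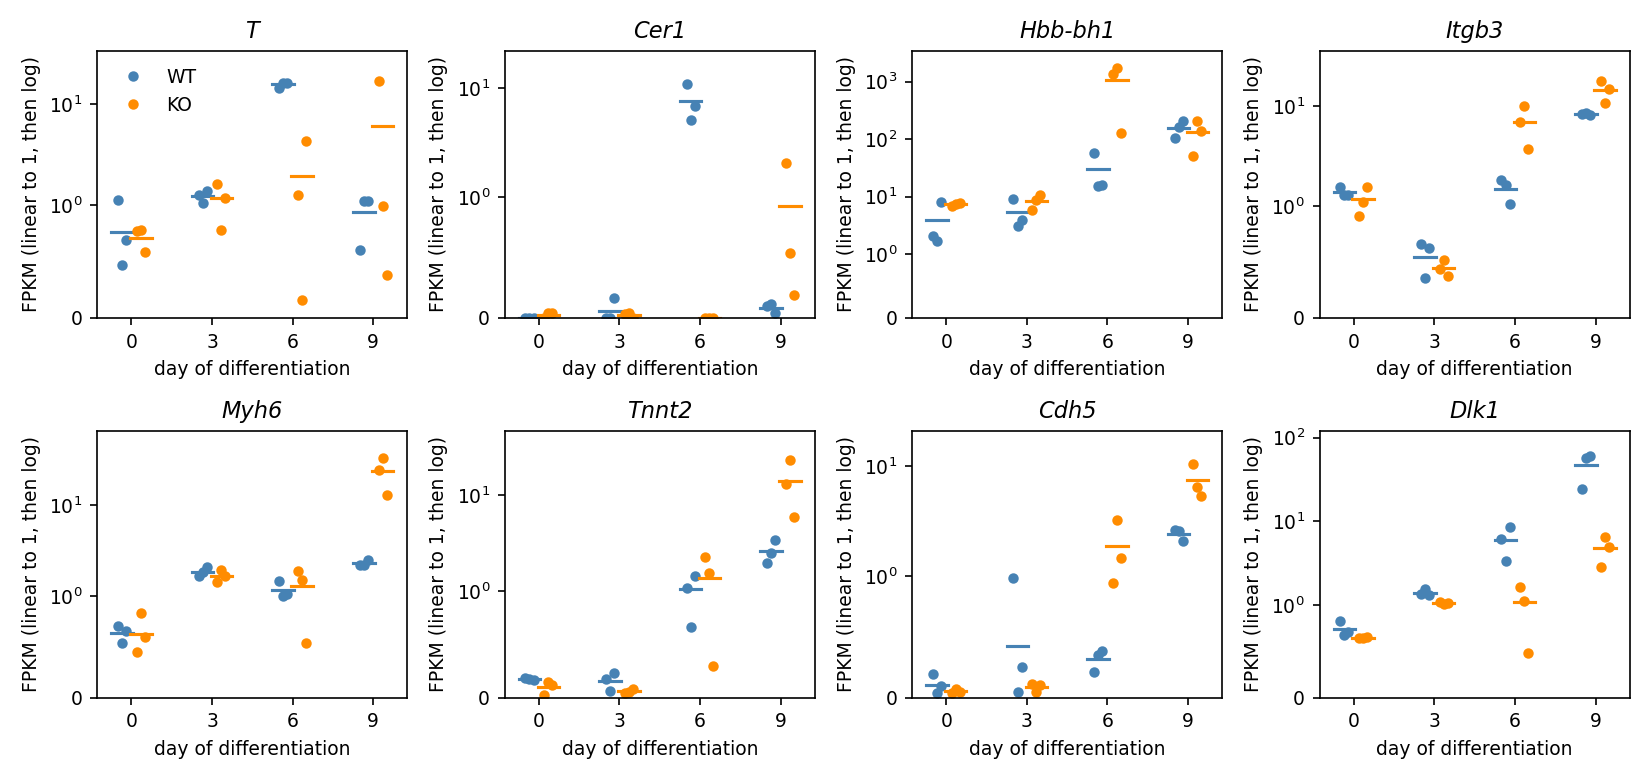
Level of T, Cer1, Hbb-bh1, Itgb3, Myh6, Tnnt2, Cdh5 and Dlk1 (FPKM, y axis, linear up to 1 and logarithmic above) by day (x axis), with WT in blue and KO in orange, dots for libraries and bars for group means. T at day 6 has means of 15.6 FPKM in WT and 1.93 in KO, and Myh6 at day 9 has means of 2.32 and 23.4.

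At day 9, KO cells had more heart muscle and endothelial gene expression than WT cells, and less of trophoblast and yolk sac genes. Myh6 (ENSMUSG00000040752, chromosome 14, 54941921 to 54966927), the atrial myosin heavy chain, was at 2.32 ± 0.170 FPKM in WT and 23.4 ± 9.95 in KO (SD, n = 3; log2 fold change 2.79, standard error 0.24, adjusted p = 9.6e-07). Cdh5 (chromosome 8, 104101625 to 104144511), the cadherin that joins endothelial cells, was at 2.43 ± 0.288 FPKM in WT and 7.41 ± 2.73 in KO (SD, n = 3; log2 fold change 1.25, adjusted p = 0.010). Rhox6 (chromosome X, 37826910 to 37829857), a homeobox gene of the placenta and germ line, was at 46.8 ± 17.7 FPKM in WT and 5.29 ± 3.49 in KO (SD, n = 3; log2 fold change -3.07, adjusted p = 4.4e-04).

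All 22 cardiac muscle genes measured had positive log2 fold changes at day 9. Of these 13 rose over all genes and 17 adjusted over the list alone (median log2 fold change 1.49, list adjusted p = 9.37e-42, 5.93e-04 with an estimated correlation). Actc1 (2.49, 40.6 ± 2.37 to 264 ± 141 FPKM), the cardiac actin, Myl7 (2.48, 52.6 to 325 FPKM), the atrial light chain, and Tnnt2 (1.91, 2.61 ± 0.719 to 14.1 ± 8.77 FPKM), cardiac troponin T, were among them. Of the 13, 7 were still called without KO replicate 1 and 8 without WT replicate 1 or without KO replicate 2. Smyd1 (1.89), a muscle methyltransferase, and Myh7 (1.84), the ventricular myosin heavy chain, also rose, and reads of Myh6 and Myh7 may be shared in part since the genes are alike. Of 16 smooth muscle genes Myocd (0.86) rose, 6 rose adjusted over the list alone and none fell (list adjusted p = 1.14e-06, 8.01e-04 with an estimated correlation), while Acta2 did not pass (log2 fold change 0.25, adjusted p = 1).

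Of 37 endothelial genes at day 9, 9 rose and none fell, and 24 rose adjusted over the list alone (median log2 fold change 0.60, list adjusted p = 1.08e-33, 0.00324 with an estimated correlation). Icam2 (1.28, 2.17 to 6.71 FPKM), Cdh5, Cd93 (1.24, 0.643 to 2.95 FPKM) and Tie1 (1.18, 1.08 to 3.80 FPKM) rose most. Pecam1 rose from 3.17 ± 0.196 to 5.92 ± 0.206 FPKM (SD, n = 3; 0.73, adjusted p = 0.047), and Kdr, at 4.39 ± 1.36 and 7.90 ± 2.92 FPKM, did not pass (0.71, adjusted p = 0.625). The arterial list was higher (1 of 12, 2 adjusted over the list alone, adjusted p = 1.12e-05, 0.0164 with an estimated correlation), with Hey1 (1.27), a Notch target, as the member that rose. The venous and lymphatic list was higher (1 of 6, 3 adjusted over the list alone, adjusted p = 6.53e-04, 0.0164 with an estimated correlation), with Aplnr (1.16), and so was the VEGF and angiopoietin list with Tie1 and Aplnr (2 of 16, 4 adjusted over the list alone, adjusted p = 8.78e-05, 0.00534 with an estimated correlation). The VEGF list shares members with the others and did not pass on its own members (adjusted p = 0.476).

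Genes of tissues outside the embryo were lower in KO cells at day 9. Of 14 trophoblast genes, Rhox6, Rhox9 (-2.16), Esx1 (-1.88) and Plac1 (-1.16) fell, 9 fell adjusted over the list alone and none rose (list adjusted p = 6.1e-16, 0.00324 with an estimated correlation). Rhox6, Rhox9, Esx1 and Plac1 all lie on chromosome X. The WT and KO lines also differ in Y-linked reads, so another difference between the lines, untested here, stays open for these genes. Rhox genes are near copies of each other, so their separate levels are less certain. Of 28 extraembryonic endoderm genes, the lysosomal protease Ctsh (-1.94) and the apolipoprotein Apoa2 (-1.45) fell, 10 fell adjusted over the list alone and none rose (list adjusted p = 2.27e-18, 0.0164 with an estimated correlation). Of 27 Hox genes 8 fell, among them Hoxc10 (-1.16), Hoxa11 (-0.98), Hoxa13 (-0.92) and Hoxd13 (-0.85), all of the posterior end of their clusters, and adjusted over the list alone 12 fell and 3 rose (list adjusted p = 9.14e-11, 0.0164 with an estimated correlation). Dlk1 (-3.01, 47.1 ± 20.1 to 4.77 ± 1.87 FPKM), an imprinted Notch-like ligand, the proteoglycan Srgn (-2.19, 14 ± 2.04 to 2.60 ± 2.09 FPKM) and the fatty acid carrier Fabp3 (-2.05, 128 ± 33.4 to 30.1 ± 7.92 FPKM) fell as well. The surface ectoderm list was lower (18 members, 2 adjusted over the list alone, adjusted p = 4.79e-06, 0.0164 with an estimated correlation), but not on members found in no other list (adjusted p = 0.380).

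In all, 146 genes passed in limma at day 9, 71 higher and 75 lower (789 at an unadjusted p under 0.05), and 21 lists passed, 10 of them with an estimated correlation. Streak (adjusted p = 0.11) and haematopoietic (adjusted p = 0.480) lists did not pass, and T stood at 6.04 ± 9.27 FPKM (SD, n = 3) in KO cells with 16.7 FPKM in replicate 1. Under TPM 89 genes passed (60 up, 29 down), with no filter 263, with the rRNA covariate 222, with a log2 fold change of at least 1 88, with a pseudocount of 0.1 36, with a stricter filter 10, without WT replicate 2 the count was 96, and with the spread taken from the 6 day 9 libraries alone 1 gene passed. Of the genes called at day 6 and day 9, 12 were called at both days and 8 of them in the same direction, 2 up and 6 down. Independent calls would give 0.164 and 0.371, but both days share 1 fit and 1 spread per gene, so their calls are not independent. The rest went in opposite directions, for which no expected number was computed. No gene was called at all 4 days, and Atf3 was the gene called at 3.

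**Figure D4:**
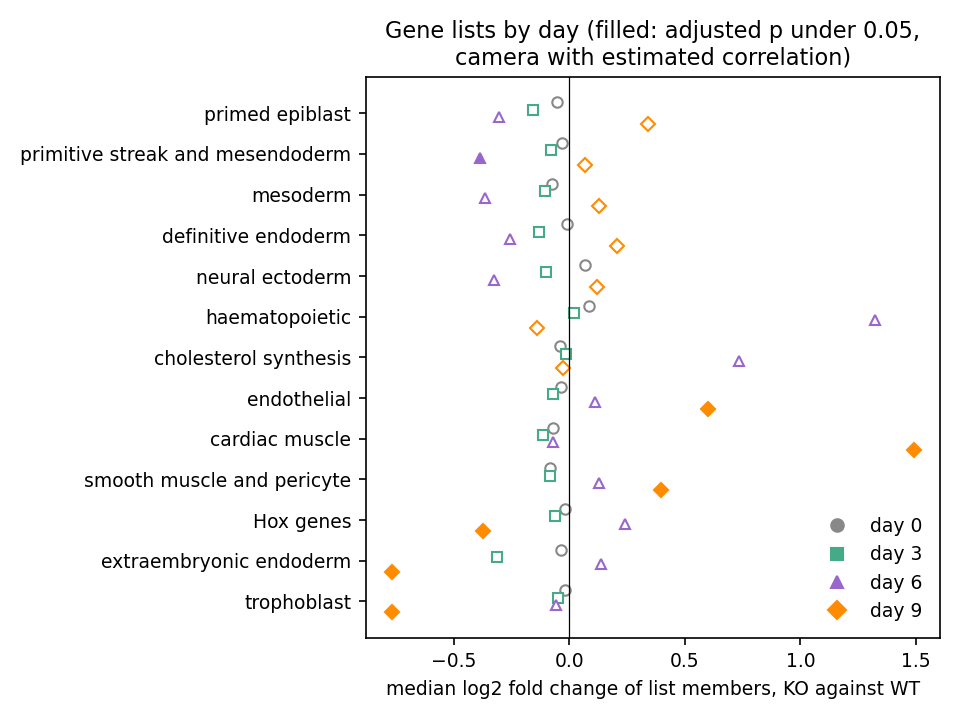
Median log2 fold change of KO against WT (x axis) over the members of 13 lists (y axis) at days 0, 3, 6 and 9. Filled symbols mark lists with an adjusted p under 0.05 by camera with an estimated correlation, such as cardiac muscle at day 9 with a median of 1.49.

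Averaged over the 4 days, the genes that differed most were Atf3 and a few genes that stood out at day 6 or 9. Atf3 had a log2 fold change of -2.58 (adjusted p = 7.19e-07), Dlk1 of -1.26 (4.6e-04), Srgn of -1.20 (0.0033), Cdkn1c, an inhibitor of the cell cycle, of -0.77 (0.0072), and Tgm1 of -0.54 (0.015), while Cer1, listed at 0 in KO cells at day 6, also passed as lower (adjusted p = 0.0473). The highest were Myh6 at 0.68 (adjusted p = 0.0174), the MAP kinase phosphatase Dusp2 at 0.60 (0.0028), Tulp3 at 0.45 (0.0281) and Myl2 at 0.38 (0.0295). In all, 30 genes passed in limma, 7 higher and 23 lower (578 at an unadjusted p under 0.05). Of 38 lists 18 passed, among them endothelial genes (higher, adjusted p = 2.3e-15), haematopoietic genes (higher, 1.5e-10), cardiac muscle (higher, 1.3e-09) and the streak (lower, 5.7e-07), and none passed with an estimated correlation (lowest adjusted p = 0.0996). Under TPM 8 genes passed (4 up, 4 down), with equal sums without the rRNA-type genes 27 (11 up, 16 down), and without KO day 6 replicate 3 the count was 55 (30 up, 25 down), which turned the balance of directions. The count was 52 with no filter, 17 with the replicate block, 10 with voom, 10 with a pseudocount of 0.1 (none up), 4 with a stricter filter, 3 with a log2 fold change of at least 1 and 2 with a block within each day. It was 17 without WT day 0 replicate 2, and 19 without any 1 of WT day 0 replicate 3, WT day 3 replicate 1 and KO day 3 replicate 2.

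The KO minus WT difference was also compared between days. Against day 0 it differed for 17 genes at day 6 (3 up, 14 down, 648 at an unadjusted p under 0.05), with Itgb3 (1.71) and Dusp2 (1.3) highest and Trh (-3.26), Sfrp1 (-2.40) and Aplnr (-2.18) among the lowest. At day 9 it differed for 40 genes (19 up, 21 down, 464 at an unadjusted p under 0.05), with Actc1 (3.25), Myh6 (2.80), Smyd1 (1.94) and Apobec2 (1.89) highest and Rhox6 (-3.10), Dlk1 (-2.93), Fabp3 (-2.35) and Rhox9 (-2.09) lowest. At day 3 it differed for 2 genes in limma (1 up, 1 down, 113 at an unadjusted p under 0.05), Nkx6-3 (0.97) and Mir7230 (listed at 0 in every group but KO day 0), which are the genes called at day 0. Atf3 itself did not pass any of these (-1.65 at day 3, -1.61 at day 6 and -2.15 at day 9, adjusted p = 1, 0.754 and 0.223). The joint test over days 3, 6 and 9 gave 90 genes (737 at an unadjusted p under 0.05), and 10 with voom. The day 6 count was 52 without KO day 6 replicate 3, with the balance turned to 35 up and 17 down, 46 without WT day 6 replicate 2, and 10 without any 1 of WT day 0 replicates 2 and 3, WT day 6 replicate 1, KO day 6 replicate 2 and the unnumbered KO day 0 library. The day 9 count was 0 with voom, 3 with a pseudocount of 0.1, 3 with a block within each day and 1 with the stricter filter. It was 61 without KO day 9 replicate 3 (43 up, 18 down), 25 without WT day 9 replicate 2 and 20 to 26 without any 1 of the 6 day 0 libraries, and with equal sums without the rRNA-type genes it was 43 (26 up, 17 down). The day 3 count was 1 without any 1 of 9 of the 12 libraries, and the joint count was 158 and 136 without KO and WT day 6 replicate 3 and 2 in that order, and 52 and 58 without WT day 9 replicate 2 and KO day 6 replicate 2.

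The KO minus WT difference at each of the 4 days was set beside the WT course across genes, which are not independent replicates. The WT change was taken between other days, from day 3 to 9 for the day 0 difference, from day 0 to 9 for days 3 and 6, and from day 0 to 6 for day 9. Its Pearson correlation with the KO minus WT difference was -0.134 at day 0 (Spearman -0.140), -0.0385 at day 3 (Spearman 0.0253), 0.134 at day 6 (Spearman 0.118) and -0.0656 at day 9 (Spearman -0.0829). At each day another split of the same 6 libraries gave a larger absolute correlation, up to 0.149, 0.236, 0.337 and 0.210. The signs at days 3 and 9 depended on single libraries: at day 3 the value was 0.0529 without WT replicate 1, 0.0188 without WT replicate 3 and 0.0815 without KO replicate 2, and at day 9 it was 0.0614 without WT replicate 3.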

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

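Tests chosen only after the result was seen were those of the day 6 genes higher and lower in KO taken apart, of the WT changes and WT peaks set beside them, of wild-type RNA in KO day 6 replicate 3, and the fits with the rRNA share as a covariate, with voom and with a block within each day.

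The KO minus WT difference changed between days for genes of several tissues, by the test of the difference itself against day 0. At day 6 the change in log2 fold change was 1.71 for Itgb3 and 1.3 for Dusp2. It was -3.26 for Trh, -2.40 for Sfrp1, -2.18 for Aplnr, -2.03 for Dll3, -2.01 for Cdkn1c and -1.88 for Foxc2. For Cer1, listed at 0 in every KO day 6 library, the difference on the log2(FPKM + 1) scale changed by -3.09. At day 9 the change was 3.25 for Actc1, 2.80 for Myh6, 1.94 for Smyd1, 1.89 for Apobec2, 1.87 for Myh7 and 1.27 for Cd93. It was -3.10 for Rhox6, -2.93 for Dlk1, -2.35 for Fabp3, -2.09 for Rhox9 and -1.82 for Esx1.

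At day 9, 10 lists also passed for the difference from day 0 by camera with an estimated correlation. Cardiac muscle (adjusted p = 2.04e-04, median change 1.55), smooth muscle (2.04e-04, 0.49), endothelial (0.00475, 0.63), VEGF and angiopoietin (0.00729, 0.22), venous (0.036, 0.55) and arterial (0.0448, 0.36) genes moved up relative to day 0. Trophoblast (0.00475, -0.82), extraembryonic endoderm (0.0448, -0.69), Hox (0.0448, -0.39) and surface ectoderm (0.036, -0.26) genes moved down. By fry, arterial, Hox and surface ectoderm (0.141 each) and extraembryonic endoderm (0.178) genes did not pass, nor did surface ectoderm (0.429) and VEGF and angiopoietin (0.299) genes on members in no other list. Over 100 splits, the real one counted among them, 4 gave at least as many genes as the real split in the day 6 interaction (17 genes, highest other 2703). It was 1, the real split itself, in the day 9 interaction (40, highest other 34) and 3 in the joint test (90, highest other 1687). These shares lie under 0.05, but chance is not excluded. Shares were taken for many comparisons, libraries may not be independent, and other splits reached 2703 and 1687 genes. The joint test's splits also ignore the pairing at day 3. The day 6 count was 10 with voom and 0 with a block within each day, the day 9 count 0 and 3, and the joint count 10 with voom. The day 6 balance turned to 35 up and 17 down without KO day 6 replicate 3. For the day 3 interaction 16 of 100 gave as many (2 genes, highest other 3), so chance was not excluded.

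The first pattern weighed was the set of 110 genes called between KO and WT cells at day 6. The share of reads in rRNA-type genes as a covariate left a median of 0.898 of the log2 fold change (quartiles 0.808 and 0.993), which argues against that share as the whole cause of these genes. Leaving out KO replicate 3 left 0.989 (quartiles 0.921 and 1.08). The genes were called with that library in the fit, which favours genes whose libraries go the same way, so this ratio does not decide its part. Calls did change: with the covariate 76 genes passed, 64 of them among the 110, and without KO replicate 3 the calls turned to 86 higher and 53 lower. If KO cells ran ahead on the WT course, called genes would go the way of the WT change from day 3 to day 9, and 50% did (50.9% of all genes), which leaves that open for the set as a whole. Of the 35 higher genes 85.7% went that way, but 66.7% of the 75 lower ones also rose in WT (Fisher's exact p = 0.0408 over genes that are not independent, 49.7% of all genes rising), so running ahead may hold for the former only in part. Of the lower ones 33.3% went that way, but this sign does not decide the question for them. In WT, 59 of the 75 were highest at day 6 of days 3, 6 and 9, counted with the values that chose them. Without WT replicate 1, 2 or 3, 65.3%, 44.9% and 64.3% of the genes called lower were highest at day 6 in the library left out (31.95%, 25.9% and 35.75% of all genes). For such genes a lower level at day 6 goes with cells ahead as with cells behind. A rule set before this count held the question open only if over 50% were highest at day 6 in each library left out, which WT replicate 2 missed. By that rule the sign counts against running ahead for the lower genes, but WT replicates 1 and 3 met it, so the question is not settled. The 10 splits are too few for a share under 0.05 (110 genes, highest other 4902), and the split with 4902 genes points to a structure of the day 6 libraries. It set KO replicate 1 and WT replicates 1 and 3 (rRNA-type share 18.6%, 18.4% and 45.6%) against the rest (11.6%, 6.10% and 12.2%), with 33 of 59 histone genes higher on the first side and 0 lower. That split called 41 of the 110 genes, not far from its share over all genes, 4902 of 15159.

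Another was the Atf3 level of KO day 6 replicate 3, 4.17 FPKM against 0.343 and 0.578 in the other libraries of its group. RNA of WT day 6 cells in that library would need a share of 24.1% to give this level. The first version of the test took 40 genes at least 4-fold apart between WT and the other KO libraries, whose median implied share of 34.2% seemed near, but genes higher in KO implied 99.7% and genes higher in WT -0.757%. The test was then restricted to the 23 genes higher in WT at day 6. Their median of -0.757% (quartiles -13.3% and 3.81%) argues against RNA of WT day 6 cells as the source, although T, 1 of the 23, implied 24.5%, near the share that Atf3 needs. WT RNA of another day was not tested. No biological explanation was tested, and some remaining Atf3 expression in that library stays open.

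The last pattern weighed was the rise of cardiac muscle genes in KO cells at day 9. With the rRNA share as a covariate the 13 called members kept a median of 1.03 of their log2 fold change, which argues against that share as the whole cause. Leaving out any 1 of the 6 libraries left at least 0.800 of the median. The members were called with all 6 in the fit, so this ratio does not decide whether 1 library is the cause. Calls were fewer, 7 of the 13 without KO replicate 1 and 8 without WT replicate 1 or KO replicate 2. Whether KO cells ran ahead of WT cells cannot be told apart from other causes, since no WT sample is later than day 9 and the correlation with the earlier WT change from day 0 to day 6, -0.0656, decides nothing. Loss of Atf3 is a candidate explanation that the design names, and another difference between the WT and KO cell lines, which also differ in Y-linked reads (1 to 444 against 0 to 3), stays open as untested.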

How the results depend on the processing

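Tests chosen only after the data were seen were those with the rRNA share as a covariate, equal sums without the rRNA-type genes, voom, blocks at day 3 and within each day, and without replicate 3 of both day 6 groups. Array weights, also chosen then, did not converge and gave no value. Depth of 4272078 reads outside rRNA-type genes in the thinnest library limits what can be seen for genes near 1 FPKM. Of 533 named gene calls, another median-of-ratios scaling lost 1, no trend 3, the rRNA covariate 16, no filter 20, equal sums without the rRNA-type genes 21, the replicate block at day 3 26, the replicate block 31, a log2 fold change of at least 1 43, voom 50, a pseudocount of 0.1 52, the compared groups alone 88, the block within each day 96 and TPM 104. Of 158 list calls, an estimated correlation lost 117, fry 78 and members in no other list 42, the block at day 3 lost 4 and gained 8, and the block within each day lost 20 and gained 20. Under TPM the median log2 fold change of all genes stood at 0.12 at day 0, 0.19 at day 3, 0.55 at day 6 and 0.24 for the mean, and at 0.78 in WT and 0.70 in KO cells at day 9 and 0.40 in KO cells at day 6. With equal sums without the rRNA-type genes it stood at 0.11 at day 6 and at -0.17 in WT cells at day 6. Directions under these scalings are relative to those medians. Except where a filter or a threshold leaves fewer genes, or a setting fewer libraries, the cause was not tested.

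Counts below are of genes called for KO against WT at days 0, 3, 6 and 9 and their mean (2, 2, 110, 146 and 30 as reported), the WT and KO changes at days 3, 6 and 9, and the interactions at days 3, 6 and 9 and all days (2, 17, 40 and 90 as reported). TPM gave 1, 0, 38, 89 and 8, then 1501 and 3554 at days 3 and 6 in WT, 1680 at day 3 in KO, and 1, 3, 16 and 40 for the interactions. A log2 fold change of at least 1 gave 88 at day 9, 3 for the mean, 1718, 3741 and 3769 in WT, 1844, 3399 and 3713 in KO, and 1 for the day 3 interaction. The compared groups alone gave 1, 0, 0 and 1 by day, 6691 in KO at day 3, and 0, 8 and 24 for the interactions. No filter gave 15, 7, 167, 263 and 52, and 5, 41, 84 and 167 for the interactions. The stricter filter gave 0, 1, 12, 10 and 4, then 1692, 3533 and 3233 in WT, 1937, 3072 and 3158 in KO, and 0, 2, 1 and 4. A pseudocount of 0.1 gave 1, 1, 36 and 10 at days 0, 3 and 9 and the mean, and 1, 3 and 29 for the interactions at days 3 and 9 and all days. The replicate block gave 61 at day 6 and 17 for the mean, and 1, 6, 22 and 46. Within each day it gave 1, 0, 49 and 2 at days 0, 3 and 6 and the mean, then 2097, 4511 and 4477 in WT, 2342, 4182 and 4315 in KO, and 0, 0, 3 and 31. Voom gave 0, 1, 52 and 10 at days 0, 3 and 6 and the mean, and 0, 10, 0 and 10. Equal sums without the rRNA-type genes, and no trend, gave 1 for the day 3 interaction, and the rRNA covariate 222 at day 9, all 146 reported genes among them. Without replicate 3 of both day 6 groups the mean gave 55, the day 6 interaction 48 and the joint test 158.

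Leaving out 1 library at a time gave 2 to 7, 0 to 2, 34 to 373 and 96 to 166 at days 0, 3, 6 and 9 and 17 to 55 for the mean. It gave 2871 to 3932, 6110 to 7358 and 6083 to 6627 in WT, 3101 to 3927, 5565 to 7321 and 5889 to 6327 in KO, and 1 to 3, 10 to 52, 20 to 61 and 52 to 158 for the interactions. Correlations with the WT course were -0.179 to -0.0791 at day 0, -0.189 to 0.0815 at day 3, 0.0056 to 0.224 at day 6 and -0.164 to 0.0614 at day 9. They turned sign at day 3 without WT replicate 1 (0.0529), WT replicate 3 (0.0188) or KO replicate 2 (0.0815), and at day 9 without WT replicate 3 (0.0614).

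Turned in direction were, under TPM, Atp5a1 (0.15) and Srebf2 (0.28) at day 9 in WT, and these lists, with adjusted p. TPM turned oxidative phosphorylation at day 6 (0.0302) and in the mean (0.00989), and the rRNA covariate did so at day 6 (0.00149) and in the mean (0.00139), and cardiac muscle in the day 6 interaction (0.0441). The stricter filter turned mesoderm at day 9 (0.883) and primitive streak in WT at day 6 (0.679) and in the interactions at days 6 (0.983) and 9 (0.758). Members in no other list turned epithelial-mesenchymal transition in WT at day 3 (0.914). Single libraries turned these lists, with the range over libraries left out after each: hypoxia and glycolysis at day 3 (without WT replicate 1, 7.47e-04, 6.62e-14 to 0.819) and its interaction (0.457, 8.41e-14 to 0.863), and primed epiblast at day 3 (without WT replicate 2, 0.561, without KO replicate 1, 0.21, 1.69e-06 to 0.561). Oxidative phosphorylation turned at day 9 (without WT replicate 3, 0.479, 6.85e-07 to 0.644), in its interaction (0.998, 1.43e-07 to 0.998) and at day 6 (without KO replicate 3, 0.0247, 0.0247 to 0.966). Naive pluripotency turned at day 9 (without KO replicate 1, 0.00178, 0.00178 to 0.973) and in its interaction (0.00846, 0.00846 to 0.987), and fibroblast and extracellular matrix at day 9 (without KO replicate 3, 0.787, 7.37e-09 to 0.787). Without replicate 3 of both day 6 groups, p53 targets (0.0277), oxidative phosphorylation (0.0314) and, in the interaction, cardiac muscle (0.0199) and p53 targets (0.019) turned. The streak list did not pass at day 6 under the stricter filter (0.74).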

Other observations

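The count of Y-linked reads and the sorting of day 3 splits by pairs were chosen only after the results were seen.

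A few imprinted growth genes were lower in KO cells, while the imprinted list as a whole was not shifted at day 6. At day 6 Cdkn1c (log2 fold change -1.77, 5.74 ± 0.94 to 1.02 ± 0.609 FPKM), Dlk1 (-1.72, 6.01 to 1.08 FPKM) and Nnat (-1.19, 106 to 45.2 FPKM) fell, and none of 31 rose over all genes, with 3 up and 3 down adjusted over the list alone. The list did not pass at day 6 (adjusted p = 0.688), where its median was 0.01 and its mean -0.05. At day 9 Dlk1 (-3.01) and Cdkn1c (-1.29, 10.1 to 3.69 FPKM) fell and Nnat did not pass (-0.05, adjusted p = 1). There the list passed as lower (adjusted p = 0.0356, 0.203 with an estimated correlation) with a median of 0.00 and a mean of -0.20. H19, among the genes with the largest rise in the WT course, did not pass at either day (-0.08 and 0.11).

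At day 6, 3 metabolic and stress lists passed as higher with the preset correlation and none with an estimated one. The 24 cholesterol synthesis genes had a median log2 fold change of 0.73, with none passing over all genes and 10 higher adjusted over the list alone (list adjusted p = 2.6e-10, 0.0570 with an estimated correlation). The unfolded protein response (20 members, 2 higher adjusted over the list alone, adjusted p = 0.0339, 0.589 with an estimated correlation) and hypoxia and glycolysis (30 members, 0 adjusted over the list alone, adjusted p = 0.0499, 0.803 with an estimated correlation) passed as higher with no member passing over all genes. At day 9 cholesterol synthesis genes did not pass (adjusted p = 0.810). Among immediate early genes Dusp2, which dampens MAP kinase signals, rose at day 6 (1.37, 1.63 ± 0.215 to 5.78 ± 0.335 FPKM) and at day 9 (1.00). That list did not pass at day 6 (adjusted p = 0.348) and passed as higher at day 9 (adjusted p = 0.00534, 0.470 with an estimated correlation). Genes of the AP-1 and CREB/ATF family, to which Atf3 belongs, did not pass as a list at either day (adjusted p = 0.513 and 0.555). Of 20 interferon response genes H2-D1 (-1.02) fell at day 9 and 3 were lower adjusted over the list alone (list adjusted p = 1.55e-04, 0.0715 with an estimated correlation).

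Other splits of the libraries were counted for each comparison of KO with WT. Over the 4 days, 1 of 100 splits, the real one itself, gave as many genes (30, highest other 16). For lists it was 4 of 100, the real split counted (18, highest other 21, median of the others 9). Both shares lie under 0.05, but chance is not excluded for either. The splits ignore the pairing of libraries at day 3, and other splits called many lists. None of the 18 lists passed with an estimated correlation (lowest adjusted p = 0.0996), and the genes fell to 2 with a block within each day and to 10 with voom. For a single day the 10 splits are too few for a share under 0.05. The real split gave 2 genes (highest other 2) and 0 lists (highest other 4) at day 0, and 2 genes (highest other 6) and 10 lists (highest other 7) at day 3. It gave 11 lists at day 6 (highest other 13), and 146 genes (highest other 1) and 21 lists (highest other 18) at day 9. The 10 splits are also too few for each day against day 0, where the real split gave 3933, 7243 and 6975 genes in WT cells (highest other 0, 2 and 0) and 4266, 6625 and 6830 in KO cells (highest other 0 in each).

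At day 3, where replicate numbers pair the libraries, 4 of the 10 splits part all 3 pairs. The real one of these gave 2 genes and 10 lists, and the others gave 0 genes and 1, 1 and 3 lists. Splits that part 1 pair gave 0 to 6 genes and 1 to 7 lists. With the replicate block at day 3, the count of genes was again 2.

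Reads of the Y-linked genes Ddx3y, Eif2s3y, Uty and Kdm5d, chosen after their values were seen, were summed per library. They came to 1 to 444 reads in the 12 WT libraries (median 53) and 0 to 3 in the 12 KO libraries (median 1), with 4 KO libraries at 0. Eif2s3y passed in limma for the mean over days (adjusted p = 0.017). A difference between the cell lines other than Atf3 was not tested and stays open for every comparison of KO with WT.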
